A study of Homo sapiens with 26 samples.

How the data were processed

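RNA of peripheral blood mononuclear cells (PBMC, the lymphocytes, monocytes and dendritic cells that stay at the interface when blood is spun over a density medium) was measured in 20 people with systemic lupus erythematosus (SLE) and 6 healthy people. SLE is an autoimmune disease with antibodies against nuclear components. Per the labels, cells were separated with Ficoll-Paque, RNA was extracted with a column kit, and polyA RNA was made into Illumina libraries and sequenced in pairs of 150 bp. Groups were taken from the disease named in each library's labels, and each number within a group names 1 library. The labels give no batch.

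Per the submitters' processing notes, BWA, TopHat2, DESeq2 and the human build hg38 were used. Their versions, roles and order, the counting program, its use of strand and the annotation of genes and endogenous retrovirus (ERV) loci are not given in the sources used here. The deposited gene values have the unit signal, gene counts divided by a size factor for each library: 100% of the nonzero values were whole multiples of the library's smallest value, within a tolerance of 0.01 of a multiple. Whole reads were therefore recovered and used in count tests as alternatives. The number of decimals in the deposited gene values (9 or 13) and their scale divided the libraries into 2 sets which, as far as the values show, had been normalized separately. Set A held 18 libraries, SLE 1 to 16 with healthy 5 and 6. Set B held 8, SLE 17 to 20 with healthy 1 to 4. On a joint median-of-ratios scale the sets lay 0.16 log2 apart. What else differed between the sets is not given in the sources used here. The 2 groups are unevenly spread over them, so each comparison was also made with a set term and within each set.

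The deposited ERV values are raw counts, although they were described as normalized. The authors' mean of each locus equalled the mean over libraries of the count divided by the gene table's size factor, within a relative tolerance of 1e-05, for 1940 of 1947 loci with a count (99.64%). Unscaled means matched for 0 loci. Among ERV counts from 1 to 20, 65.92% were even (61.16% to 70.98% per library). The design written before the data were examined assumed normalized values and named edgeR as the test for raw counts, so edgeR was used for ERV loci. The deposited comparisons hold log2 fold changes and their errors, a Wald score and p-values with adjusted values from DESeq2, per the file headers. The authors' ERV fold changes have healthy over SLE as their sign and the gene fold changes SLE over healthy. The signs were checked against the group means, and values of SLE over healthy are printed throughout. The authors' gene means matched joint size factors over all 26 libraries for 84.468% of 39537 genes, and the deposited values for 0.01%.

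The gene table had 62069 genes, of which 17266 had a mean of 10 or more over the 26 libraries. XIST, TSIX and Y-linked genes were not tested, and 1 gene with a blank value in 1 library was left out. Of the 17263 genes tested, 14911 had a symbol in the deposited table, 1835 were named by identifier from GENCODE release 29 (hg38), and 517 had no symbol. Positions are those of that release, counted from 1. Genes were tested with limma on log2(value + 1), with a trend in the prior variance and robust estimation. Fold changes are on this scale and understate the change of genes with low values. ERV loci with a mean of 5 or more (578 of 3220) were tested with edgeR's quasi-likelihood test, with the authors' gene size factors as library sizes. The standard error of an ERV log2 fold change was its size divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. All tests were two-sided.

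For each library, the total ERV level was log2 of the summed scaled counts, and a locus was detected at a scaled count of 1 or more. Both were compared by exact permutation over all 230230 splits into 20 and 6 libraries. With a set term, labels were exchanged within sets (10710 splits, or 5355 without healthy 3). For 22 gene lists fixed before the data were examined, the score of a library was the mean of log2(value + 1) over tested members, centred per gene, and lists needed 3 tested members. Scores were compared by the same exact permutation, adjusted over the lists. The lists covered the responses to interferon alpha and beta and to interferon gamma, markers of plasmablasts, B cells, T cells, NK cells, monocytes, plasmacytoid and conventional dendritic cells, mature neutrophils, immature granulocytes, platelets and erythroid cells, cell cycle genes, immediate early genes, inflammatory cytokines, retroelement silencing, retroelement restriction, nucleic acid sensing, complement, ribosomal proteins and mitochondrial-encoded genes. Camera with an estimated correlation and fry were the alternative list tests. Within SLE, the ERV level was related to each list score by Pearson's r and Spearman's rho with 100000 permutations. Set-term values of single genes and of single ERV loci used joint size factors. Counts of ERV calls with a set term used the authors' factors unless joint size factors are named.

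Named genes followed a rule written before the data were examined. It took the 5 largest positive and the 5 largest negative fold changes among genes past the threshold with a mean of 50 or more, without immunoglobulin and T cell receptor variable segments and genes without a symbol. From each list it took the 2 members with the largest change past the threshold, or else the 1 with the smallest p. The result of 1 gene named by this rule is not reported here. For ERV loci it took the 5 largest changes in each direction past the threshold.

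Alternatives written before the data were examined were pseudocounts of 0.5 and 5, no filter and a filter at 50, limma without trend and robust estimation, an exact rank-sum test, TMM rescaling, quantile normalization, edgeR and DESeq2 on recovered reads, marker scores of T cells, B cells and monocytes as covariates, the label number as a block, ERV counts scaled to their total, other sums of ERV counts, and each library left out in turn. Set terms, joint size factors, single sets, limma on ERV loci and fits without healthy 3 were added after the data were seen. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

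The tests were tried on counts simulated from the means, size factors and dispersions of the real libraries, with 200 changed features. The simulation held no difference between the sets, no correlation between genes and no deficit of ERV counts in healthy 3. Its false calls therefore do not give the error rate in these data. Among 17263 genes, limma recovered 37.3%, 58.2% and 87.9% of changes of 1.5-, 2- and 4-fold, with 3 false calls among 126. False calls numbered 9 among 118 for limma with a set term, 4 among 133 for edgeR and 20 among 160 for DESeq2. Among 578 ERV loci, edgeR recovered 3%, 34.3% and 75.8%, and with a set term 1.5%, 13.4% and 62.1%. The permutation, rank-sum and adjustment code passed 5 of 5 checks. Depth was 19.0 to 32.1 M recovered gene reads per library (M, mega). ERV loci overlap in sequence, and reads that fit several of them could be split or counted more than once by a step that is not given here. Positions of ERV loci were not used here, so loci are named only as the authors named them.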

Results

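The transcriptome of peripheral blood mononuclear cells (PBMC) was compared between 20 people with systemic lupus erythematosus (SLE) and 6 healthy people, 1 library each. Gene expression and counts at endogenous retrovirus (ERV) loci, the remnants of ancient retroviral insertions in the genome, were given in separate tables. Depth was 27.8 ± 3.37 M gene reads in SLE (M, mega; SD, n = 20) and 28.7 ± 1.63 M in healthy libraries (n = 6). Hemoglobin genes took 0.391% ± 0.592 of the gene table in SLE and 0.0304% ± 0.0254 in healthy libraries. Mitochondrial-encoded genes took 5.62% ± 1.61 and 6.81% ± 1.21. The ERV table held 143542 ± 24493 counts per SLE library and 116451 ± 44807 per healthy library, of which healthy 3 held 30246 and the other healthy libraries 106354 to 146810. As far as the values show, set A (SLE 1 to 16, healthy 5 and 6) and set B (SLE 17 to 20, healthy 1 to 4) had been normalized separately. No 2 libraries of the same group were alike within sampling noise, the closest being SLE 2 and SLE 3 (chi-square of 30.4 per gene). Pairs across the groups were not compared.

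The first comparison asked which genes differed between SLE and healthy PBMC. The 5 largest increases included 3 genes of the interferon alpha and beta response list. IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116698), an interferon-induced mitochondrial protein, was at 1435 ± 1853 normalized counts in SLE (n = 20) and 13 ± 3.28 in healthy libraries (n = 6). Its log2 fold change was 5.17 (SE 1.03, limma adjusted p = 0.0103), and 18 of 20 SLE libraries lay above every healthy library. IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145) was at 11300 ± 7924 and 1025 ± 499 (log2 fold change 2.98, SE 0.71, limma adjusted p = 0.0212). OTOF (ENSG00000115155, chromosome 2, 26457203 to 26558698), which encodes the calcium sensor otoferlin, rose by 3.25 (SE 0.86).

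The long non-coding RNA LINC00487 (ENSG00000205837, chromosome 2, 6728177 to 6770311) rose by 3.37 on the log2 scale (SE 0.73) and the sialidase gene NEU4 (ENSG00000204099, chromosome 2, 241808825 to 241817413) by 3.05 (SE 0.83). NEU4 varied widely among healthy libraries (64.3 ± 121 normalized counts, against 141 ± 107 in SLE). The largest decreases were in SIGLEC17P (ENSG00000171101, chromosome 19, 51167328 to 51173524), a pseudogene of the sialic acid-binding lectins, which fell by 1.67 (SE 0.36), and FEZ1 (ENSG00000149557, chromosome 11, 125442881 to 125592568), an adaptor of microtubule transport, which fell by 1.52 (SE 0.37). EEF1A1P6 (ENSG00000233476, chromosome 7, 22510616 to 22511999) fell by 1.45 (SE 0.33). It is a processed copy of the translation elongation factor EEF1A1, with which it can share reads, so its value is uncertain. LILRA4 (ENSG00000239961, chromosome 19, 54333185 to 54339150), a receptor of plasmacytoid dendritic cells, fell by 1.41 (SE 0.31), and the anion exchanger SLC4A3 (ENSG00000114923, chromosome 2, 219627327 to 219641980) fell by 1.37 (SE 0.32). All of these genes passed limma's threshold, with adjusted p between 0.0103 and 0.0339. With joint size factors and a set term, NEU4 and EEF1A1P6 did not pass (limma adjusted p = 0.0924 and 0.0760).

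In all, 851 of 17263 genes passed limma's threshold, 683 higher and 168 lower in SLE (80.3% higher). The split depended on scaling: it was 455 to 306 with joint size factors (59.8% higher), 416 to 345 with TMM (54.7%), 377 to 369 with quantile normalization (50.5%), 340 to 405 with edgeR on recovered reads (45.6%) and 1003 to 626 with DESeq2 (61.6%). Within set A limma called 0 genes (1584 had an unadjusted p under 0.05), and within set B 1304 (806 higher, 498 lower). A set term with joint size factors left 292 calls (173 higher, 119 lower), of which 152 higher and 42 lower genes were also called without it, and edgeR with a set term called 319. Single healthy libraries moved the count: 61 genes were called without healthy 3, 67 without healthy 2, 174 without healthy 4, 277 without healthy 1 and 2385 without healthy 5. Of the 29 named genes past the threshold, 4 still passed without healthy 3 (IFI27, LILRA4, CLEC4C and PROK2), 3 without healthy 2 (IFI27, LINC00487 and PROK2), 8 without healthy 4 and 15 without healthy 1. IFI27 and PROK2 passed in all 26 omissions. The authors' deposited table called 1809 genes (1150 higher, 659 lower), of which 734 were also called here, all in the same direction.

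For genes induced by interferon alpha and beta, the antiviral cytokines, the score over 45 genes was 1.51 higher on the log2 scale (0.35 ± 0.96 in SLE, n = 20, and -1.16 ± 0.26 in healthy libraries, n = 6; exact permutation p = 0.00086, adjusted p = 0.00946), and 17 of 20 SLE libraries lay above every healthy library. With an estimated correlation (camera) the list did not pass (adjusted p = 0.263). Of the members, 28 rose, none fell and the others did not pass. Adjusted over the list alone, 41 rose. Besides IFI27 and IFI44L they included RSAD2 (viperin, an inhibitor of viral replication), which rose by 2.48 (SE 0.60, limma adjusted p = 0.0212), and ISG15, a ubiquitin-like modifier, which rose by 1.999 (SE 0.47, limma adjusted p = 0.0212). Both were chosen as examples after their values were seen. The difference was 1.42 within set A (exact permutation p = 0.0654) and 2.19 within set B (exact permutation p = 0.0286, the smallest its 70 splits allow). With a set term it was 1.83 (exact permutation adjusted p = 0.0144).

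The list leaning to interferon gamma, which holds chemokines, guanylate-binding proteins and antigen-processing genes, was 0.54 higher (exact permutation adjusted p = 0.0328). With an estimated correlation the list's adjusted p = 0.386. Of its 19 members, 1 rose, and 9 did when adjusted over the list alone. That member was FCGR1B, which rose by 1.16 (SE 0.29, limma adjusted p = 0.0250) and is nearly identical to the IgG receptor gene FCGR1A, so the 2 can share reads. It did not pass with a set term (limma adjusted p = 0.0980). The difference was 0.43 within set A (exact permutation p = 0.216), 0.61 within set B (exact permutation p = 0.0286) and 0.52 with a set term (exact permutation adjusted p = 0.0458). The list did not pass with TMM or with joint size factors, nor without healthy 1, 2, 3 or 5 (highest exact permutation adjusted p = 0.0805).

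**Figure D1:**
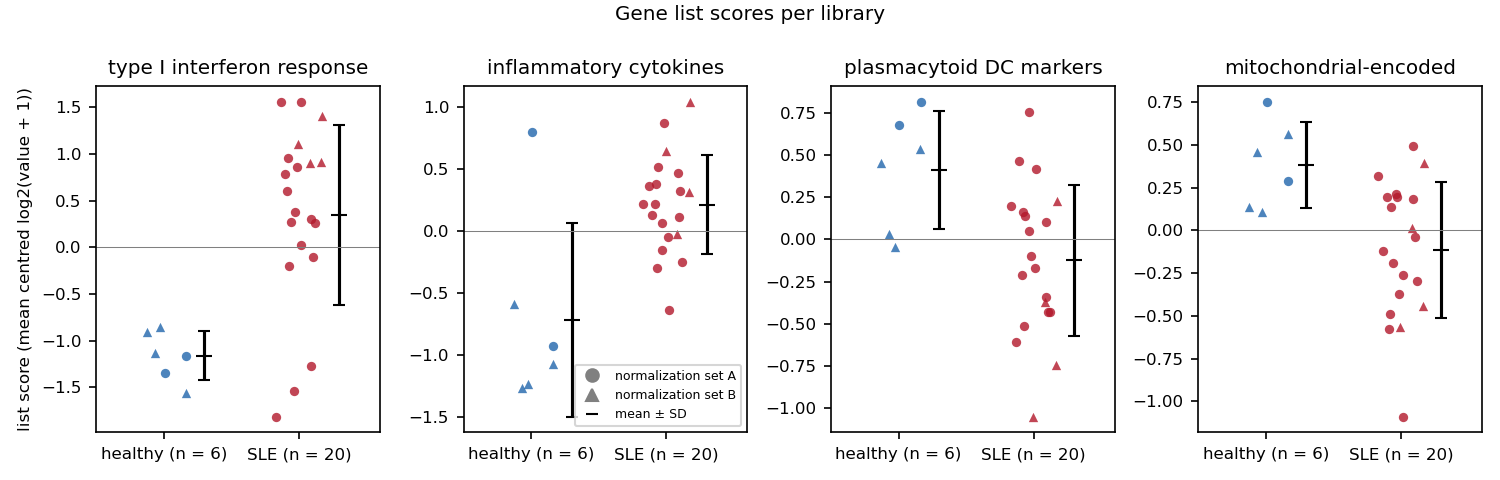
Scores of 4 gene lists, each as the mean centred log2(value + 1) over the tested members (y axis), in healthy (blue, n = 6) and SLE (red, n = 20) libraries. Points are libraries, with circles for set A and triangles for set B, and bars are the mean ± SD; the interferon score was 0.35 ± 0.96 in SLE and -1.16 ± 0.26 in healthy libraries.

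Inflammatory cytokine genes scored 0.93 higher in SLE (0.21 ± 0.40, n = 20, and -0.72 ± 0.78, n = 6; exact permutation adjusted p = 0.00946). With an estimated correlation it did not pass (camera adjusted p = 0.289). Of 14 tested members, 5 rose and 6 did when adjusted over the list alone. The 5 were the neutrophil-attracting chemokine genes CXCL1 (which rose by 1.65, SE 0.41), CXCL2 (1.48, SE 0.43), CXCL3 (1.47, SE 0.43) and IL8 (1.42, SE 0.39), and NFKBIA, an inhibitor of NF-kB (0.79, SE 0.20). TNF and IL1B, the inflammatory cytokines of monocytes, were at log2 fold changes of 0.07 (SE 0.37) and 0.44 (SE 0.42) and did not pass (limma adjusted p = 0.940 and 0.564). Healthy 5 stood apart from the other healthy libraries in this score (0.80, others -1.27 to -0.59). The difference was 0.21 within set A (exact permutation p = 0.536), 1.54 within set B (exact permutation p = 0.0286) and 0.91 with a set term (exact permutation adjusted p = 0.0401). CXCL2 itself was at -0.20 within set A and did not pass with a set term (limma adjusted p = 0.181), nor did CXCL1 (0.0562), CXCL3 (0.148), IL8 (0.121) and NFKBIA (0.0860). With a set term, 1 other member of the list passed and was higher in SLE.

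Immediate early genes, which respond within minutes to stimulation and to handling of cells, scored 0.69 higher (exact permutation adjusted p = 0.0328). The list's adjusted p = 0.386 with an estimated correlation. Of 15 members 2 rose, and 5 did when adjusted over the list alone. EGR3, a transcription factor of activated lymphocytes, rose by 1.91 (SE 0.42, limma adjusted p = 0.0169), and ATF3, a stress-response factor, rose by 1.13 (SE 0.33, limma adjusted p = 0.0440). The direction differed between the sets, at -0.34 within set A (exact permutation p = 0.216) and 1.02 within set B (exact permutation p = 0.0286), and with a set term the difference was 0.38 (exact permutation adjusted p = 0.288). ATF3 was at -0.09 within set A and 1.82 within set B. Neither EGR3 nor ATF3 passed with a set term (limma adjusted p = 0.0734 and 0.159). Without healthy 1, 2, 3 or 4 the list did not pass (highest exact permutation adjusted p = 0.103).

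Mature neutrophil markers scored 0.83 higher in SLE (exact permutation adjusted p = 0.0394), but did not pass with an estimated correlation (camera adjusted p = 0.386). Of 12 members 1 rose, and 3 did when adjusted over the list alone. PROK2, a chemotactic peptide of neutrophils, was at 659 ± 316 normalized counts in SLE (n = 20) and 199 ± 100 in healthy libraries (n = 6), a log2 fold change of 1.75 (SE 0.27, limma adjusted p = 0.00108), and 19 of 20 SLE libraries lay above every healthy library. It also passed with a set term (limma adjusted p = 0.00983). The list difference was 0.94 within set A (exact permutation p = 0.105), 0.54 within set B (exact permutation p = 0.314) and 0.73 with a set term (exact permutation adjusted p = 0.127). The list did not pass with TMM, with joint size factors or as a median over members, nor without any 1 of the healthy libraries or of SLE 4, 6, 10, 12, 17 and 18 (highest exact permutation adjusted p = 0.0910). The list of immature granulocyte genes, which are made in bone marrow precursors, did not pass (difference 0.92, exact permutation adjusted p = 0.239). Its member ARG1, the arginase of granulocytes, rose by 1.19 (SE 0.32, limma adjusted p = 0.0328), and was the 1 member of 20 that passed both over all genes and adjusted over the list alone. With a set term ARG1 was at 0.74 and did not pass (limma adjusted p = 0.171).

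Both dendritic cell lists were lower in SLE by exact permutation. With an estimated correlation (camera) neither passed (adjusted p = 0.263 for each). Markers of plasmacytoid dendritic cells, the main producers of interferon alpha, scored lower by -0.53 (exact permutation adjusted p = 0.0328), and 3 of 8 tested members fell, also when adjusted over the list alone. LILRA4 was at 119 ± 64.9 normalized counts in SLE (n = 20) and 285 ± 69.8 in healthy libraries (n = 6), with 19 of 20 SLE libraries below every healthy library. CLEC4C, a lectin that marks these cells in blood, fell by 1.32 (SE 0.27, limma adjusted p = 0.0126). Markers of conventional dendritic cells, which present antigen to T cells, scored lower by -0.75 (exact permutation adjusted p = 0.0328). Of 8 members 1 fell and 2 did when adjusted over the list alone. CD1C, which presents lipid antigens, fell by 0.96 (SE 0.24, limma adjusted p = 0.0227) and did not pass with a set term (limma adjusted p = 0.0732).

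The plasmacytoid difference was -0.78 within set A (exact permutation p = 0.0131), -0.73 within set B (exact permutation p = 0.0857) and -0.75 with a set term (exact permutation adjusted p = 0.0144). The conventional difference was -1.08 within set A (exact permutation p = 0.0392), -0.69 within set B (exact permutation p = 0.200) and -0.88 with a set term (exact permutation adjusted p = 0.0401). The plasmacytoid list did not pass without healthy 1, 2, 5 or 6 (highest exact permutation adjusted p = 0.0915), and the conventional list without healthy 2, 3, 5 or 6 (highest 0.103).

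Markers of the most abundant PBMC types did not differ detectably. The scores of T cells (-0.03), B cells (-0.08) and monocytes (0.07) each had an exact permutation adjusted p of 0.883. The T cell kinase LCK (log2 fold change -0.35, SE 0.17) and the B cell receptor component CD79B (-0.35, SE 0.33) had the smallest p of their lists and did not pass. No member of the T cell, B cell, NK cell, plasmablast, platelet or cell cycle lists passed, over all genes or adjusted over the list alone. The monocyte list's median and score lay above 0 and its camera test pointed down. The T cell score was 0.27 within set A and -0.17 within set B, the B cell score 0.14 and -0.36, and the monocyte score -0.24 and 0.23.

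Erythroid markers, which include the globin genes, differed by 2.21 in score without passing (exact permutation adjusted p = 0.0553). No member passed over all genes, and 7 of 10 rose when adjusted over the list alone. ALAS2, the erythroid enzyme of heme synthesis, was at 1851 ± 3544 and 55.0 ± 34.5 normalized counts (limma adjusted p = 0.0917). The list passed without SLE 3, 5, 7, 8, 13 or 20 (lowest exact permutation adjusted p = 0.0338). Complement genes (0.62, exact permutation adjusted p = 0.0753) had 0 of 13 members past limma's threshold over all genes and 2 that rose when adjusted over the list alone, with CD55, which protects cells from complement, at 0.36 (SE 0.12, limma adjusted p = 0.0744). The list passed without SLE 5 (lowest exact permutation adjusted p = 0.0364).

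Cell cycle genes differed by 0.78 (exact permutation adjusted p = 0.111, and 0.0399 without SLE 3), with the replication helicase gene MCM4 at 0.65 (SE 0.23). NK cell markers were at -0.65 (exact permutation adjusted p = 0.131, and 0.0392 without SLE 11), with the activating receptor KLRF1 at -1.09 (SE 0.41). Markers of plasmablasts, the antibody-secreting cells, were at 0.73 (exact permutation adjusted p = 0.217), with the folding enzyme TXNDC5 at 1.40 (SE 0.52). Platelet markers were at 0.24 (exact permutation adjusted p = 0.663) and at -0.31 with a set term, with the von Willebrand factor receptor subunit GP9 at 0.76 (SE 0.49). Within sets A and B, in that order, the differences were 1.75 and 2.01 for erythroid, 0.38 and 0.80 for complement, 0.96 and 0.98 for cell cycle, -0.45 and -1.08 for NK cell, 0.54 and 1.34 for plasmablast, -0.18 and -0.43 for platelet and 0.92 and 0.05 for immature granulocyte lists.

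Ribosomal protein genes scored lower in SLE by -0.50 (exact permutation adjusted p = 0.0328). The list's adjusted p = 0.263 with an estimated correlation. Of 37 members 3 fell, and 31 did when adjusted over the list alone. RPL5 fell by 0.62 (SE 0.18, limma adjusted p = 0.0462) and RPS14 by 0.54 (SE 0.15, limma adjusted p = 0.0399). Neither passed with a set term (limma adjusted p = 0.261 and 0.215). Both have processed copies in the genome that can share their reads. The difference was -0.35 within set A (exact permutation p = 0.157), -0.08 within set B (exact permutation p = 0.543) and -0.21 with a set term (exact permutation adjusted p = 0.172). The list did not pass without healthy 1, 2, 3 or 4 (highest exact permutation adjusted p = 0.0805).

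Mitochondrial-encoded genes, which specify subunits of the respiratory chain, scored lower by -0.50 (exact permutation adjusted p = 0.0328). The list's adjusted p = 0.263 with an estimated correlation. Of 13 members 2 fell, and 5 did when adjusted over the list alone. MT-ND4L fell by 1.03 (SE 0.25) and MT-ATP6 by 0.79 (SE 0.20). With a set term they were at -0.60 and -0.65 and did not pass (limma adjusted p = 0.114 and 0.109). Each overlaps a neighbouring gene on the mitochondrial chromosome, so reads of the overlap are uncertain. The difference was -0.63 within set A (exact permutation p = 0.0654), -0.46 within set B (exact permutation p = 0.114) and -0.54 with a set term (exact permutation adjusted p = 0.0401). The list did not pass as a median over members, nor without healthy 2, 3 or 5 (highest exact permutation adjusted p = 0.0805).

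**Figure D2:**
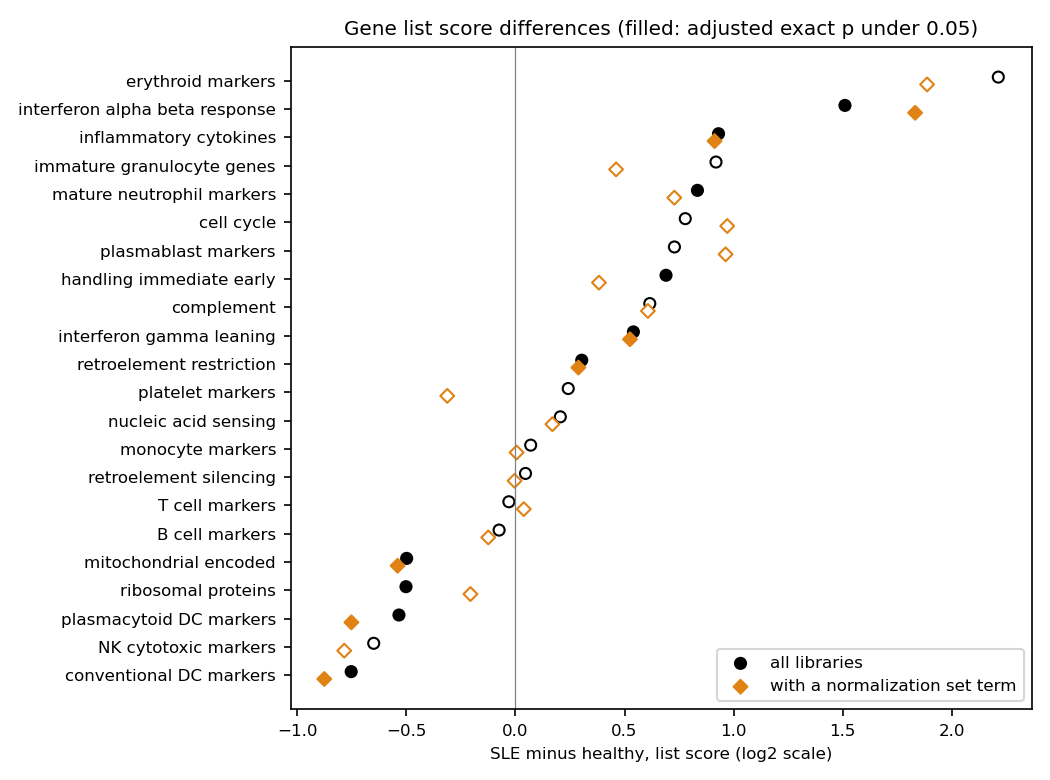
Difference in score between SLE (n = 20) and healthy (n = 6) libraries on the log2 scale (x axis) for 22 gene lists (y axis), over all libraries (black circles) and with a set term (orange diamonds). Filled symbols have an exact permutation adjusted p under 0.05, as the interferon alpha and beta list had at 1.51 and 1.83.

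Among genes that act on retroelements, the result for those that restrict them depended on scaling. The restriction list, which holds the APOBEC3 cytidine deaminases and other nucleic acid enzymes, scored 0.30 higher (exact permutation adjusted p = 0.0328), but did not pass with TMM, with joint size factors or as a median over members. Camera, with an estimated correlation, gave an adjusted p of 0.510. Of 17 members 3 rose. Adjusted over the list alone 5 rose and 1 fell. APOBEC3A, a deaminase of single-stranded DNA, rose by 1.46 (SE 0.37), ADAR, an editor of double-stranded RNA, rose by 0.61 (SE 0.14), and the antiviral zinc finger gene ZC3HAV1 rose by 0.37 (SE 0.09). ZC3HAV1 did not pass with a set term (limma adjusted p = 0.114). APOBEC3A resembles APOBEC3B over part of its length and can share reads with it. The difference was 0.35 within set A (exact permutation p = 0.105), 0.24 within set B (exact permutation p = 0.0857) and 0.29 with a set term (exact permutation adjusted p = 0.0401). The list did not pass without healthy 1, 2 or 5 (highest exact permutation adjusted p = 0.0805).

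Genes that silence retroelements through chromatin did not differ as a group (0.05, exact permutation adjusted p = 0.466; 0.10 within set A and -0.10 within set B). Of 22 members 2 rose, and 4 rose and 1 fell when adjusted over the list alone. ATF7IP, a partner of the histone methyltransferase SETDB1, rose by 0.46 (SE 0.10, limma adjusted p = 0.0174), and FAM208A, a subunit of the HUSH silencing complex, rose by 0.25 (SE 0.07, limma adjusted p = 0.0425). FAM208A did not pass with a set term (limma adjusted p = 0.179). The list's score and median lay above 0 and its camera test pointed down. Nucleic acid sensing genes did not differ as a group (0.21, exact permutation adjusted p = 0.162; 0.17 within set A and 0.17 within set B). Of 15 members 1 rose, and 4 rose and 2 fell when adjusted over the list alone. MB21D1, which encodes the cytosolic DNA sensor cGAS, rose by 0.47 (SE 0.11, limma adjusted p = 0.0212) and did not pass with a set term (limma adjusted p = 0.0760).

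The second comparison asked which ERV loci differed. Of 578 loci tested with edgeR, 25 were higher in SLE and 0 were lower, and the median log2 fold change of all tested loci was 0.71. The largest increases were at locus 1109, with 12 ± 8.28 scaled counts in SLE (n = 20) and 1.08 ± 1.36 in healthy libraries (n = 6; log2 fold change 3.36, SE 0.77, edgeR adjusted p = 0.0104), and at locus 3951, with 14.5 ± 8.49 and 1.49 ± 1.56 (3.25, SE 0.62, edgeR adjusted p = 0.00292). Locus 466 followed with 450 ± 300 and 60.9 ± 38.2 (2.88, SE 0.64, edgeR adjusted p = 0.00843), then loci 3797 (2.73, SE 0.81) and 5430 (2.71, SE 0.80), both with an edgeR adjusted p of 0.0464. At locus 3951, 19 of 20 SLE libraries lay above every healthy library, and at locus 466, 17.

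Healthy 3 held far fewer ERV counts than the other libraries, and 9 of the 25 loci were called without it. Calls numbered 6 with a set term and 6 with a set term and without healthy 3, in each case loci among the 25. With joint size factors, the 6 called with a set term and without healthy 3 were 3317, 1495, 466, 510, K-46 and 3951. This group was singled out after their values were seen, and each passed in all 26 omissions of 1 library. Locus 3317 was at 896 ± 267 scaled counts in SLE (n = 20) and 311 ± 129 in healthy libraries (n = 6), with 20 of 20 SLE libraries above every healthy library. Locus 1495 was at 635 ± 281 and 194 ± 74.9, locus 510 at 94.0 ± 52.5 and 17.9 ± 17, and locus K-46 at 54.8 ± 20.7 and 13.9 ± 12.6. Within set A edgeR called 0 loci (78 had an unadjusted p under 0.05), and within set B 4, or 4 without healthy 3.

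The split of ERV calls also depended on scaling. It was 25 to 0 with the authors' factors, 8 to 1 with TMM on the ERV table, 10 to 4 with counts scaled to the ERV total and 24 to 7 with DESeq2's own factors, and these settings brought the median of all loci to 0.18, 0.33 and 0.17. Single libraries moved the number of calls by over 1.5 times: it fell without healthy 3 (9 calls), healthy 2 (11), healthy 1 (12), SLE 3, 8, 14 or 16 (15 each) and SLE 2, 7 or 15 (16 each), and rose without SLE 18 (91), healthy 5 (62), healthy 6 (52), SLE 13 (42) and SLE 19 (39). The authors' deposited table called 124 loci, all higher in SLE, of which 110 were tested here and 25 called. A repeat of DESeq2 with the authors' factors over all loci called 120 of those 124, and 45 without healthy 3, when all 124 still had a log2 fold change above 0.

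**Figure D3:**
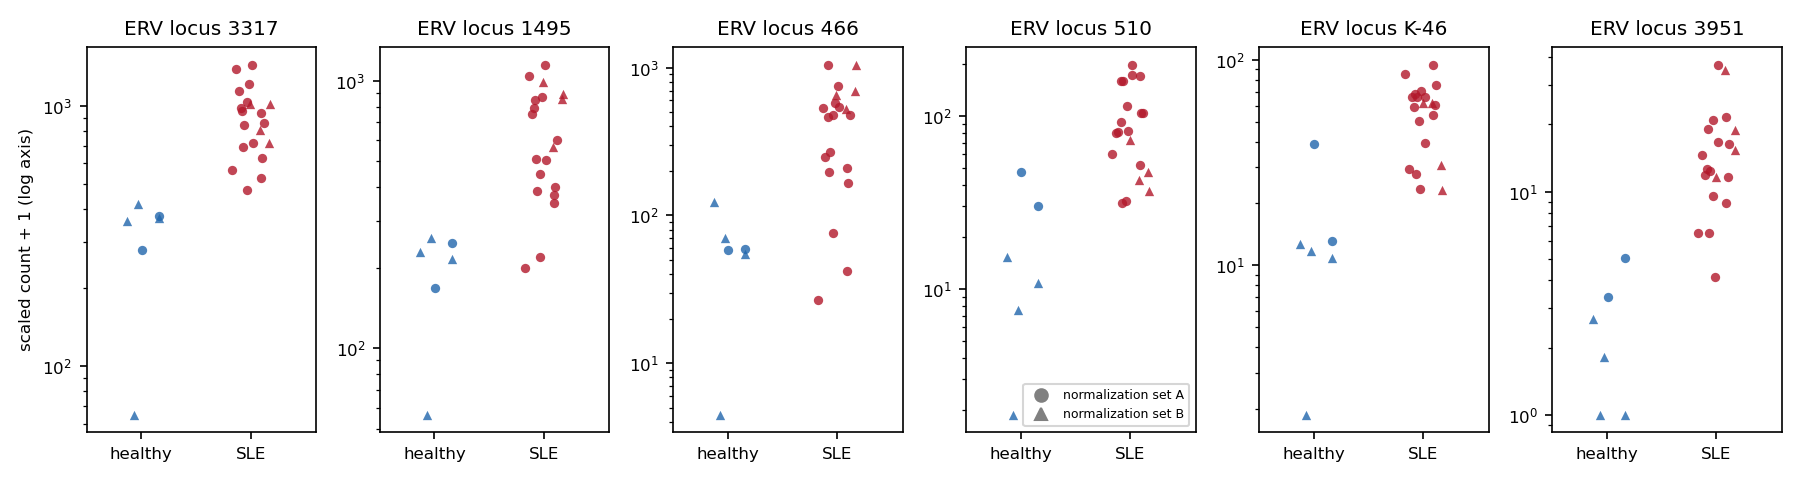
Scaled counts + 1 on log axes (y axis) at the 6 ERV loci called with joint size factors, a set term and without healthy 3, in healthy (blue, n = 6) and SLE (red, n = 20) libraries. Points are libraries, with circles for set A and triangles for set B; at locus 3317 all 20 SLE libraries lay above every healthy library.

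The third comparison was of the ERV level as a whole. The summed scaled counts were 140313 ± 12552 in SLE (n = 20) and 106877 ± 39910 in healthy libraries (n = 6), a ratio of 1.47 on the log scale (log2 difference 0.56, exact permutation p = 0.000426). Without healthy 3 the healthy mean was 123021 ± 6006 (n = 5) and the log2 difference 0.19, a ratio of 1.14 (exact permutation p = 0.00504). The log2 difference was 0.16 within set A (exact permutation p = 0.0719), 0.63 within set B (exact permutation p = 0.114) and 0.08 within set B without healthy 3 (exact permutation p = 0.200). With a set term it was 0.41 (exact permutation p = 0.00962), and with a set term and without healthy 3 it was 0.12, a ratio of 1.09 (exact permutation p = 0.0198).

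Loci detected numbered 866 ± 87.7 in SLE (n = 20) and 744 ± 150 in healthy libraries (n = 6; exact permutation p = 0.0183). The difference of 122 loci was 63.8 without healthy 3 (exact permutation p = 0.137), 46.8 with a set term (exact permutation p = 0.391) and 7.84 with a set term and without healthy 3 (exact permutation p = 0.786). It was 67.6 within set A (exact permutation p = 0.131) and 28.3 within set B (exact permutation p = 1.0). Within set B without healthy 3 the direction turned, at -54.2 (exact permutation p = 0.0286, the smallest its 35 splits allow). In set B, SLE libraries held at most 25.4 M gene reads and healthy libraries 29.4 M or more. SLE 17 to 20 held 100146 to 120707 ERV counts, and healthy 1, 2 and 4 held 140684 to 146810. Depth therefore cannot be told apart from SLE in the numbers of loci detected within set B.

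**Figure D4:**
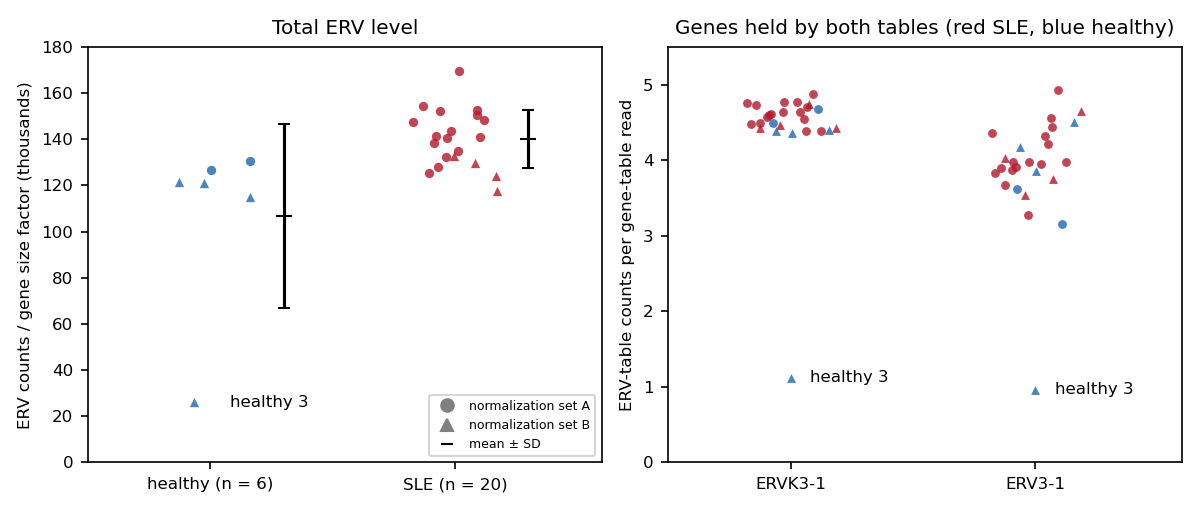
Left, summed ERV counts divided by the gene size factor, in units of 1000 (y axis) in healthy (blue, n = 6) and SLE (red, n = 20) libraries, with the mean ± SD. Right, ERV-table counts per gene-table read of ERVK3-1 and ERV3-1; points are libraries, circles for set A and triangles for set B, and healthy 3 lay lowest in each, at 1.12 and 0.961 counts per read.

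The last comparison asked whether, within SLE, libraries with a higher list score had a higher total ERV level. Of 22 lists, 0 passed by permutation test after adjustment, for Pearson's r or Spearman's rho over all 20 SLE libraries, and 1 had an unadjusted p under 0.05. That was the plasmablast list (r = -0.47, permutation p = 0.0374, adjusted p = 0.661, and rho = -0.46, permutation p = 0.0436, adjusted p = 0.959). Without the 2 libraries farthest from the median score r was -0.50 (permutation p = 0.0343), and within set A alone it was -0.45 (n = 16, permutation p = 0.0796). It was -0.34 with the ERV level as mean log2 over loci (permutation p = 0.141) and -0.19 as a share of the gene table sum (permutation p = 0.429). The interferon alpha and beta scores fell into separate clusters, 3 SLE libraries at -1.27 or below and 17 at -0.20 or above. Within the 17, r was -0.35 (permutation p = 0.171, adjusted p = 0.679) and rho -0.30 (permutation p = 0.243, adjusted p = 0.987). The 17 included the 4 SLE libraries of set B, with interferon scores of 0.90 to 1.40. Their mean log2 ERV level was 16.94, against 17.13 in the SLE libraries of set A. The sets were not separated in this r, so a difference between them may enter it. Set B held 4 SLE libraries, too few for a correlation.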

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

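The tests of partial ERV counting and of sequencing depth in healthy 3 were chosen only after the result was seen. Among 66 groups of healthy values examined, 5 had 1 library whose gap to its nearest neighbour was large against the range of the group, and chance gives such a gap in about 1 in 20 groups. The total ERV level of healthy 3 was 14.67 on the log2 scale against 16.81 to 17 in the other healthy libraries (gap 0.9206 of the range). Healthy 3 had 452 detected ERV loci against 751 to 886 (gap 0.6889). Locus 466 lay at 2.16 on the log2 scale in healthy 3 against 5.78 to 6.95 (gap 0.7554). In healthy 5 the inflammatory cytokine score was 0.80 against -1.27 to -0.59 (gap 0.671). CXCL2, a member of that list, was at 10.1 on the log2 scale in healthy 5 against 5.60 to 6.82 (gap 0.7253).

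In healthy 3, all 168 ERV loci with a mean of 50 or more in the other healthy libraries were lower, with a median log2 difference of -2.33. Shallow sequencing is argued against, since healthy 3 held 29.68 M gene reads (M, mega), within the range of the other healthy libraries (26.3 to 30.4 M). Less ERV RNA in these cells is also argued against: genes that followed 52 loci over the other libraries (r of 0.9 or more) predicted a median shift of -0.2708, where -2.22 was observed, and 52 of 52 loci lay below their prediction. A candidate explanation that the values fit is that only part of this library's reads entered the ERV count. For ERVK3-1 and ERV3-1, which both tables hold, healthy 3 had 1.12 and 0.961 ERV-table counts per gene-table read, 4.08 and 4.14 times below the median of the other libraries (ranges 4.36 to 4.88 and 3.15 to 4.93), while its gene-table levels were 837 normalized counts, somewhat below the other healthy libraries (975 to 1559), and 392, within their range (300 to 532). What would have kept reads out of the count stays open.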

How the results depend on the processing

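The fits with set terms, joint size factors, single sets, without healthy 3, with limma on ERV loci and with all loci in DESeq2 were chosen only after the data were seen, and the cause of a change was not tested unless stated. Against 851 genes, limma called 284 with a set term, 292 with joint size factors and a set term, 472 with no filter (more genes tested), 1533 with cell marker covariates, 0 within set A (1584 at unadjusted p under 0.05; 2 healthy libraries) and 1304 within set B. The exact rank-sum test called 385, DESeq2 1629 and edgeR with a set term 319. Omitting 1 library gave 61 to 2385. Against 25 ERV loci, edgeR called 6 with a set term and 6 when healthy 3 was left out too, 7 and 6 with joint size factors and a set term, 9 with TMM and 2 without healthy 3, 14 scaled to the ERV total, 15 with cell marker covariates, 11 with a filter at 50 (195 loci tested), 45 with no filter, 0 within set A (78 at unadjusted p under 0.05), 4 within set B and 4 there without healthy 3. The exact rank-sum test called 46, limma 114 (112 and 96 with pseudocounts of 0.5 and 5, 114 without trend), limma after quantile normalization 17, and DESeq2 with the authors' factors over all loci 129, or 45 without healthy 3. Omitting 1 library gave 9 to 91. The total ERV level differed by 0.56 (omissions 0.19 to 0.65), with all omissions past the threshold, but not within set A (0.156), within set B (0.627), there without healthy 3 (0.0799), or as mean log2 over loci without healthy 3 (0.459). The difference in detected loci (122, omissions 63.8 to 150.6) was 46.8 with a set term, 7.84 without healthy 3 too, 67.6 within set A, 28.3 within set B, and reversed to -54.2 there without healthy 3. Of 22 list scores 10 passed (omissions 2 to 12), 7 each with TMM, with joint size factors, with a set term, with both and as a median over members, 11 with a pseudocount of 5, 12 by fry and 0 by camera with an estimated correlation (2 at unadjusted p under 0.05), where the interferon alpha and beta difference is the same 1.51 (omissions 1.43 to 1.62). Members past the threshold numbered 54, and 133 adjusted over the list alone.

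Of the values past the threshold, ATF3 (-0.0858), CXCL2 (-0.203) and the immediate early list (-0.337) turned direction within set A. Also within set A, CD79B was at 0.128 and GP9 at -0.288. GP9 was at -0.0546 with a set term, -0.0470 with joint size factors too and -0.0206 in edgeR with a set term. The T cell score was 0.0380 with a set term and 0.0455 with joint size factors too, and the platelet score -0.313 and -0.305. The monocyte score was -0.0093 with TMM and in camera -0.0698. The silencing score was -0.0151 as a median, -0.0042 with a set term, -0.0233 with joint size factors, -0.0330 with TMM and in camera -0.0459. Camera values have the size of the score and the sign of the test. Omitting 1 library gave -0.158 to 0.0503 for the B cell, -0.138 to 0.0352 for the T cell and -0.0316 to 0.166 for the monocyte score.

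The label numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.1736, -0.0628, -0.057, -0.0916, -0.0707 and 0.0335, and 1 of 6 healthy libraries correlated best with its own number. With the replicate number as a block over 12 libraries, limma called 0 genes (3432 at unadjusted p under 0.05) and edgeR 43 ERV loci. Apart from omissions, results of the comparisons were labelled the same 44 times, weaker 29 times, stronger 13 times and reversed 1 time. These include numbers of calls, which were labelled by their size and have no direction or side of the threshold. Values of single genes, loci and lists kept their direction and side of the threshold 695 times. They were weaker 226 times, stronger 11 times and reversed 18 times. Of simulated 2-fold changes, edgeR recovered 34.3% among ERV loci and 65.7% among genes, where limma recovered 58.2%. Whether depth accounts for the lower recovery at ERV loci was not tested.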

Other observations

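The relations of ERV loci to the interferon score, the set-term values of ERV loci and of both gene lists, and the search for the genes nearest to each locus were tests chosen only after the results were seen. The ERV loci higher in SLE differed in how they varied among SLE libraries. Among the 17 SLE libraries in the larger cluster of interferon scores, locus 1495 rose with the score (r = 0.86, permutation p = 5e-05, adjusted over 578 loci p = 0.0289; rho = 0.85; r = 0.85 without the 2 farthest libraries; r = 0.87 in the 13 of set A). Set B held too few of these libraries for a value. Loci 3317 (r = 0.76, permutation p = 0.00044) and 466 (r = 0.72, permutation p = 0.00144) passed when adjusted over the 25 called loci alone (adjusted p = 0.0055 and 0.012) but not over all 578 (adjusted p = 0.127 and 0.199). Locus 4224 varied in the opposite sense (r = -0.66, adjusted over the 25 called loci p = 0.0143), and did not pass over all 578 either (adjusted p = 0.199). The gene with the highest correlation was HERC6, an interferon-induced ubiquitin ligase, for locus 1495 (r = 0.95), IRF7, the transcription factor that drives interferon alpha production, for locus 3317 (r = 0.92), and the interferon-induced long non-coding RNA NRIR for locus 466 (r = 0.96). Few or none of the maxima over all genes under permutation reached these values (permutation p = 0.000999, 0.002 and 0.000999). Of the 10 best-correlated genes, 8, 5 and 3 were in the interferon alpha and beta list. Over the 25 libraries other than healthy 3, the best-correlated gene of locus 3317 was IFIT5 (r = 0.97), also of that list. HERC6 and NRIR stayed the best for loci 1495 and 466. Positions of the loci were not used, so reads of such a gene counted at a locus cannot be told apart from ERV RNA. The same search of genes for the other loci called with a set term and without healthy 3 went otherwise. Few permuted maxima reached the highest r of loci 510 (r = 0.93, permutation p = 0.00300) and K-46 (r = 0.88, permutation p = 0.0180). Many reached that of locus 3951 (r = 0.74, permutation p = 0.738). For each of these loci, 0 of the 10 best-correlated genes were in the list.

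For the ERV loci higher in SLE, chance was tested first. Of 100 splits into 20 and 6 libraries, 2 gave at least as many calls as the real one, itself included (25 calls, highest other split 171). These splits ignored the sets, over which the groups are uneven, so their count cannot exclude chance. The split with 171 calls points to a structure among the libraries. It had 2 of its 6 libraries in set A, as the real split has, but 2 other splits as uneven over the sets called 0 loci, so the source of its calls stays open. With joint size factors, a set term and no healthy 3, 1 of 100 splits within the sets, the real one, gave as many (6 calls, highest other 3). This argues against chance, in a setting added after the data were seen. For the other 19 called loci, following the interferon response cannot be told apart from other causes: 0 of the 19 passed with r above 0, but 1 of all 578 loci did, and their median r of -0.31 was that of all loci (-0.31; 18 of 19 and 482 of 578 had r below 0, and within set A 6 of the 19 had r above 0). Healthy 3 and the sets together cannot be told apart from SLE for these 19. Their median log2 fold change was 2.18 (median SE 0.58) before and 1.418 (median SE 0.54) after removing both, the latter with joint size factors. The loci were chosen by their calls in the same libraries, so a value above 0 decides nothing. Their calls ended as the fold shrank at a similar SE. For the 6 loci called with a set term and without healthy 3, following the interferon response may account for part of them, but 1 of 6 passed, so it cannot be told apart from other causes at this number of libraries, and SLE itself was not tested apart from interferon.

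The gene calls of SLE against healthy were weighed against the sets, since SLE libraries of set A and set B differed from each other in 3603 genes (1750 higher and 1853 lower in set A; limma, 16 against 4 libraries). Of 100 splits, 2 gave at least as many calls as the real one, itself included (851 calls, highest other 871). These splits ignored the sets too, so their count cannot exclude chance. The split with 871 calls drew 5 of its 6 libraries from set B, so the sets may have given its calls. However, 4 other splits with 2 libraries in set A, as in the real one, called 0 genes. With a set term, 1 of 100 splits within the sets, the real one, gave as many (292 calls, highest other 54). This argues against chance, in a setting added after the data were seen. Of 657 calls that ended with a set term, 61.95% had the same sign between the SLE libraries of set A and of set B (84.9% of the 126 lower, 56.5% of the 531 higher genes, 54.3% of all genes). This lies between the bounds set beforehand. Among the 194 calls kept with a set term it was 28.35%. Both groups of genes were chosen by a term fitted in part to the same SLE libraries, so these shares decide nothing. For the 657 calls the sets cannot be told apart from SLE. For the interferon alpha and beta list the sets are argued against, as its difference was 1.831 with a set term and 1.51 without. For the immediate early list, 0.3826 with a set term against 0.69 without, a difference between the sets remains possible and cannot be told apart from SLE, because set A held 2 healthy libraries and the list differed in sign between the sets.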
